A study of Mus musculus with 5 samples.

How the data were processed

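SUZ12, a core subunit of the Polycomb repressive complex PRC2, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse embryonic stem cells (ESCs) whose Mbd3 gene is knocked out. MBD3 is a subunit of the NuRD chromatin remodelling complex. Per the labels, 4 libraries differ in what the knockout cells carried, named GFP, WT, deltaMBD and deltaCC. GFP is taken here as the control without MBD3 and WT as full-length MBD3, since the labels give the names alone. The series design describes the other 2 (ΔMBD and ΔCC below) as forms of MBD3a that lack the methyl-CpG-binding domain or the coiled-coil domain. An input library without antibody, from cells labelled EBRTcH3, completes the 5 samples. It has no peak table here and entered no comparison.

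Single-end reads were produced on a NextSeq 500, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.18.0.12, MACS2 and the mouse build mm9. The aligner, the MACS2 version and settings, and the peak threshold are not given in the sources used here, and neither is the use of the input as control. Per the file headers, the peaks of each library were linked to genes with GREAT version 3.0.0 by its rule of the nearest genes on both sides, within 5000 bp at most, with curated regulatory domains added. Each deposited table has 1 line per gene with the names of the linked peaks and the signed distance of each peak from the transcription start site in bp, which GREAT measures from the peak's midpoint. A positive distance lies downstream of the start site. The deposited tables hold no other unit than this distance: no coordinate, width, height, fold enrichment, p-value or read number is given in them. The depth of the libraries is therefore unknown, and so is the strength of any peak. Peaks were listed per library, and no pooling is recorded.

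A gene was counted as listed in a library when at least 1 peak was linked to it within 5 kb of its start site. A peak is linked only to the nearest gene on each side. In dense clusters such as Hox, a peak within 5 kb of a gene can thus go unlinked to it when another start site lies between. Below, a peak within 5 kb of a gene means a linked peak. Pairs farther away came from 7 genes and were left out of every comparison of lists. Their distances served only to place peak centres in the HoxD cluster, and they are described in the closing section. Lines that repeated a gene symbol were joined. Of the 1942 symbols in any deposited table, 1833 matched a symbol of the RefSeq gene table (GRCm38.p6) and 59 matched 1 synonym. The 50 others were kept under the names in the files. Among them were 3 names that a spreadsheet had turned into dates, which were not assigned to a gene. The RefSeq table served for names, the number of 21900 protein-coding symbols, and which genes neighbour each other. Coordinates on mm9 are not used here, since no annotation of that build was at hand.

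With 1 library per group, no comparison has a replicate check and no p-value is given. Shares carry an exact 95% binomial (Clopper-Pearson) interval, which covers counting error over genes or peaks only, not the spread between cultures. A difference between libraries is thus a difference between these lists, and is not separated from chance between cultures. Libraries were compared by the genes listed in both, and by the peaks of a library with a peak of the other centred within 1 kb at the same gene. All shares of peaks are out of the peaks listed within 5 kb of a gene, not of all peaks called. Overlap by 1 bp, the planned criterion, needs widths and could not be computed. To describe whether a list of genes stood apart, its share was set beside 10000 random sets of WT genes matched on the number of WT peaks, with 4 or more as a single class (seed 7). The functions were tested on simulated data made from the WT gene names. Of 1000 shared genes among 1664, 1000 were recovered, and of 400 peaks placed near their partner, 400 were recovered. The analysis used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

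Before the data were examined, 10 lists with 183 genes were fixed: the Hox clusters, trophectoderm, endoderm, mesoderm, neuroectoderm, developmental ligands, cell cycle inhibitors, germline, pluripotency and housekeeping genes. The rule for named genes, fixed at the same time, took list members whose status differed between libraries, the 8 strongest peaks present in a list and absent from the other, the 5 strongest peaks of each list, and Mbd3 and Suz12. Strength is not given in the files, so the number of peaks at a gene replaced it for these peaks, with ties in alphabetical order. That replacement was chosen after the files were seen. A gene's number of peaks depends on how broad regions were split by the caller, and is not a measure of binding strength. Some genes that the rule names are not reported here. Alternatives were a window of 1 kb, all deposited pairs, genes with at least 2 peaks, leaving out the Hox genes, leaving out mitochondrial, interferon zeta and Gm-numbered genes, counting a neighbouring gene as a match, centres within 500 bp, and joining peaks within 1 kb.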

Results

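To ask how the genomic sites of SUZ12 depend on the form of MBD3, SUZ12 ChIP-seq peaks were compared between 4 cultures of Mbd3-knockout mouse ESCs, labelled GFP, WT, ΔMBD and ΔCC, with 1 library each. Peaks were listed within 5 kb of 1051 genes in the GFP library, 1664 in WT, 1677 in ΔMBD and 1221 in ΔCC. These genes were linked to 1893, 2671, 2986 and 2243 distinct peaks, in the same order. The highest peak number was 2905 in GFP, 4097 in WT, 4546 in ΔMBD and 3558 in ΔCC, which is the least number of peaks called in each library. Between 63.1% and 65.7% of these numbers appeared in the tables, so about the same part of each call set lay near a start site. Numbers of reads are not given, and differences in depth between the libraries are unknown. Neither Mbd3 nor Suz12 was listed in any library, and a SUZ12 peak table offers no check of the Mbd3 deletion itself.

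Regulators of cell lineages were listed in all 4 libraries far more often than protein-coding genes at large, and no member of the short housekeeping and germline lists was listed. Of the 21900 protein-coding symbols, 4.61% were listed in GFP, 7.32% in WT, 7.37% in ΔMBD and 5.37% in ΔCC. By contrast, 25 of 28 neuroectoderm genes, 10 of 16 trophectoderm genes, 11 of 16 endoderm genes, 11 of 20 mesoderm genes and 19 of 24 ligand genes were listed in every library. Cdx2 and Eomes, transcription factors of the trophectoderm, were listed in every library, and so were Gata4, Gata6 and Sox17 of the endoderm, T (Brachyury) of the mesoderm, and Pax6 and Olig2 of the neural lineage. The peak closest to the Gata6 start site lay at +1619 bp in GFP, +1756 bp in WT, +1143 bp in ΔMBD and +1515 bp in ΔCC. None of the 14 housekeeping genes and none of the 9 germline genes was listed in any library. The intervals of these shares reach 23.2% and 33.6%, above the 4.61% to 7.37% of protein-coding genes at large. These lists are thus too short to show depletion. Of 13 pluripotency genes, Esrrb alone was listed, in every library, and Pou5f1, Nanog and Sox2 were in none.

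**Figure D1:**
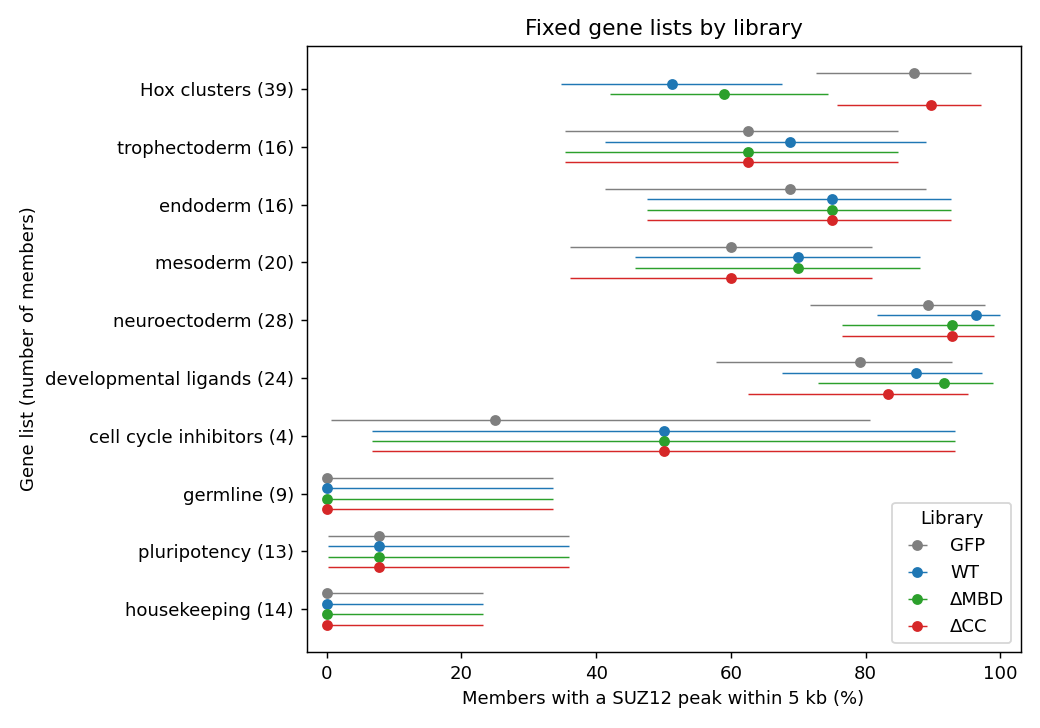
Share of each fixed gene list with a SUZ12 peak within 5 kb of the start site, in percent (x axis), for the lists named on the y axis with their numbers of members. Points are the single libraries GFP, WT, ΔMBD and ΔCC and bars are exact 95% binomial intervals for counting error; the intervals of each lineage list overlap across libraries, and the Hox list was at 51.3% in WT and 89.7% in ΔCC.

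The comparison of WT with GFP asks which SUZ12 sites are listed when MBD3 is put back. Of the 1664 WT genes, 979 (58.8%, interval 56.4 to 61.2) were also listed in GFP and 685 were not. Of the 1051 GFP genes, 93.1% (91.5 to 94.6) were listed in WT and 72 were not. At the level of peaks, 43.5% of WT peaks had a GFP peak centred within 1 kb, and 65.9% of GFP peaks had a WT peak. Members of the fixed lists were present in both directions. Those listed in WT and not in GFP were 12, among them Hoxb1, Tfap2c (an AP-2 transcription factor of the trophectoderm), Cxcr4 (a chemokine receptor), the mesoderm genes Mesp1, Tbx3 and Kdr, the neural transcription factors Neurod1 and Otx1, the ligands Bmp4 and Fgf15, and Cdkn2a, which encodes the cell cycle inhibitor p16 and the protein ARF. Those listed in GFP and not in WT were 17, of which 16 were Hox genes; the other was Mixl1, a mesendoderm transcription factor with a peak at -462 bp.

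Outside the fixed lists, the genes missing from GFP with the most WT peaks were Kazald1, Kremen2 (a receptor for Dickkopf proteins, which inhibit Wnt signalling), Nxph4, Paqr4, Tfap2d and Zic5, with 5 WT peaks each, and Adm (adrenomedullin) with 4, as had Cdkn2a. Of the WT-not-GFP genes, 15 had at least 4 WT peaks. In the other direction, Hoxb3 had 7 GFP peaks and no WT peak. Gm13275, Gm13288 and Ifnz, members of the interferon zeta gene cluster, had 5 each, as had Hoxb4, Hoxc6 and Tbr1, a T-box transcription factor of the brain. Gm13276, of the same interferon cluster, had 4. The interferon zeta genes are near-identical copies in tandem, and reads can be divided between them, so their peaks are uncertain.

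Lineage genes of the WT list were kept in GFP more often than other WT genes. Of the 85 members of the trophectoderm, endoderm, mesoderm, neuroectoderm and ligand lists that were listed in WT, 76 (89.4%) were also listed in GFP. Random WT genes with the same numbers of peaks gave a median of 61.2%, with 95% of the draws between 50.6% and 70.6%. In ΔCC, 80 of the 85 (94.1%) were listed, against a random median of 68.2% (58.8 to 77.6). In ΔMBD, 83 (97.6%) were listed, against 91.8% (84.7 to 96.5). These percentages describe the 4 libraries and carry no test between conditions. The random genes were not matched on the distance of their peaks. At 1 kb, the WT list kept 48 of these 85 genes, against 1215 of all 1664. WT genes with 1 peak were kept in GFP at 45.1% when centred within 1 kb and at 65.6% when farther. Part of the difference may therefore go with distance. With a window of 1 kb the lineage and ligand lists held 50 genes in GFP, 48 in WT, 50 in ΔMBD and 44 in ΔCC, so the order of the libraries at 5 kb, with 77, 85, 84 and 80 genes, did not hold at 1 kb.

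The ΔMBD library asks whether SUZ12 sites are listed without the methyl-CpG-binding domain. Its gene list was close to that of WT. Of the WT genes, 1497 (90.0%, interval 88.4 to 91.4) were also listed in ΔMBD, and these were 89.3% (87.7 to 90.7) of the 1677 ΔMBD genes. Peaks were matched within 1 kb for 77.2% of WT peaks and 72.2% of ΔMBD peaks. Among the 167 WT genes missing from ΔMBD, Serpine2, a serine protease inhibitor, had 4 WT peaks. Myo5b (a myosin motor), Ntn3 (a netrin) and Tbc1d24 had 3 each, and Adcy1, Asic4, Cdh3 and Chsy1 were the first in the alphabet of those with 2. In all, 21 of the 167 had at least 2. The 180 ΔMBD genes missing from WT were led by Gm10837, Il15ra and Phospho1 with 3 peaks. Acan (aggrecan), Aldh1a3, Bcor (the BCL6 corepressor), Card10 and Clec11a followed with 2 each, among 26 genes with at least 2. Of the fixed lists, Tfap2c, Otx1, Hoxa13, Hoxb7, Hoxc8 and Hoxd3 were in WT and not in ΔMBD, and Fgf10 and 7 Hox genes were in ΔMBD and not in WT.

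The ΔCC library asks the same for the coiled-coil domain. Of the WT genes, 1097 (65.9%, interval 63.6 to 68.2) were listed in ΔCC and 567 were not. The share of ΔCC genes listed in WT was 89.8% (88.0 to 91.5). Peaks were matched within 1 kb for 52.0% of WT peaks and 66.4% of ΔCC peaks. Among the 567 missing genes, Tbx3, Kiss1r (the kisspeptin receptor), Nfil3 (a bZIP transcription factor), Nt5e (an ecto-nucleotidase), Mpped1, Gm3164 and Serpine2 had 4 WT peaks each, and A930004D18Rik was the first in the alphabet of those with 3. In all, 39 of the 567 had at least 3. All but Serpine2 of these 8 were listed in ΔMBD, and none in GFP. Of the fixed lists, Tbx3, Kdr, Neurod1 and Bmp4 were in WT and ΔMBD and in neither GFP nor ΔCC, and Tfap2c was in WT alone. The 124 ΔCC genes missing from WT were led by Gm13283 with 7 peaks, Bcor and Gm13275 with 6, and Gm13276, Hoxb4, Hoxd13 and Ifnz with 5, followed by Gm13271 with 4. They included 15 Hox genes.

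Between the mutants, 1112 genes were shared, which were 91.1% (interval 89.3 to 92.6) of the ΔCC list and 66.3% (64.0 to 68.6) of the ΔMBD list. The ΔCC list shared 968 genes with GFP. These were 79.3% (76.9 to 81.5) of the ΔCC list and 92.1% (90.3 to 93.7) of the GFP list, and ΔCC held 253 genes that GFP did not. Of the fixed lists, Hoxa3, Hoxa7 and Mixl1 were in GFP and not in ΔCC, and genes in ΔCC and not in GFP included Hoxb1, Hoxd10, Cxcr4, Mesp1, Otx1, Fgf15 and Cdkn2a. Tbx3, Kdr, Neurod1, Bmp4 and Fgf10 were in ΔMBD and not in ΔCC, and Otx1 and 12 Hox genes were in ΔCC and not in ΔMBD. The genes shared by ΔCC and GFP made up 74.2% of the genes in either list, against 61.4% for ΔCC and WT, 81.2% for ΔMBD and WT, and 56.8% for ΔMBD and GFP. Such a share cannot exceed the length of the shorter list divided by that of the longer. The lists held 1051 genes in GFP, 1221 in ΔCC, 1664 in WT and 1677 in ΔMBD. Pairs of similar length can thus reach higher values, and these shares do not separate likeness from list length. Of the GFP peaks, 73.6% (71.5 to 75.6) had a ΔCC peak within 1 kb, against 65.9% for WT and 67.5% for ΔMBD. With 2243 peaks in ΔCC, 2671 in WT and 2986 in ΔMBD, this order was not that of list length. By genes it did not hold: 92.1% of GFP genes were listed in ΔCC, 93.1% in WT and 94.0% in ΔMBD.

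Over the 4 libraries, 1935 genes were listed at least once. The largest set, 900 genes, was listed in every library, and the next, 368 genes, was listed in WT and ΔMBD and not in GFP or ΔCC. With a window of 1 kb these sets held 401 and 310 genes, so the first depended more on the window. A further 169 genes were in every library but GFP, 133 in WT alone and 130 in ΔMBD alone. Of the 685 genes listed in WT and not in GFP, 537 (78.4%, interval 75.1 to 81.4) were listed in ΔMBD and 184 (26.9%, 23.6 to 30.3) in ΔCC. In 169 of the 685 both mutants had a peak, in 368 ΔMBD alone, in 15 ΔCC alone, and in 133 neither. Of the 979 genes listed in WT and GFP, 98.1% were listed in ΔMBD and 93.3% in ΔCC. Of the 72 genes listed in GFP and not in WT, 28 (38.9%, 27.6 to 51.1) were listed in ΔMBD and 55 (76.4%, 64.9 to 85.6) in ΔCC. Of the 567 WT genes missing from ΔCC, 501 (88.4%, interval 85.4 to 90.9) were also missing from GFP, against 233 for independent lists of these lengths. The overlap was not particular to ΔCC: of the 167 WT genes missing from ΔMBD, 148 (88.6%, 82.8 to 93.0) were also missing from GFP, against 68.7 for independent lists. All losses were read against the same WT library, so part of each excess may come from WT peaks that were chance calls.

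**Figure D2:**
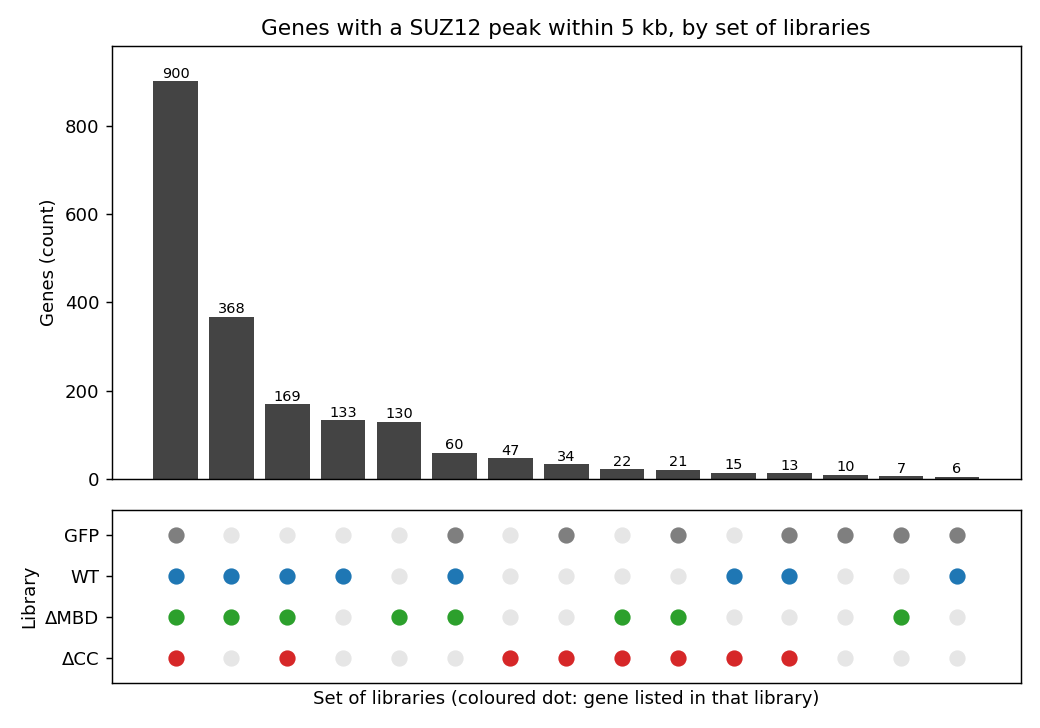
Number of genes with a SUZ12 peak within 5 kb (y axis, count) for each set of libraries that listed them (x axis); coloured dots mark the libraries GFP, WT, ΔMBD and ΔCC of a set. The sets of 900 genes in all libraries and 368 genes in WT and ΔMBD only are the largest; with a window of 1 kb they held 401 and 310 genes.

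The Hox genes, which encode the transcription factors of the body axis and are textbook targets of Polycomb, were listed more often in GFP and ΔCC than in WT and ΔMBD. Of the 39 Hox genes, 34 were listed in GFP, 20 in WT, 23 in ΔMBD and 35 in ΔCC, and 14 were listed in every library. In HoxA, 9 of 11 genes were listed in GFP, 5 in WT, 6 in ΔMBD and 8 in ΔCC. In HoxB, the numbers were 9, 6, 7 and 10 of 10, and in HoxC 9, 7, 8 and 9 of 9. In the HoxD cluster, 7 of 9 genes were listed in GFP and 8 in ΔCC, against 2 in WT and 2 in ΔMBD. Hoxd8, Hoxd9, Hoxd12, Hoxd13, Hoxa11, Hoxb3 and Hoxb4 were listed in GFP and ΔCC only. Hoxb1 went the other way, with peaks in every library but GFP. Hoxc8 had 8 peaks in GFP, 1 in WT, none in ΔMBD and 8 in ΔCC. Outside the clusters, Foxd3, a forkhead transcription factor of the neural crest, had 7, 1, 1 and 7 peaks in the same order. With a window of 1 kb the Hox genes listed were 22 in GFP, 15 in WT, 10 in ΔMBD and 20 in ΔCC, so ΔMBD then held fewer than WT.

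Peaks linked to more than 1 gene, distant links included, place the peak centres of the HoxD cluster on a common scale. From -14.3 kb to 21.8 kb around the Hoxd13 start site, 9 peak centres lay in GFP, 1 in WT, 2 in ΔMBD and 11 in ΔCC. Both ends of this range are the outermost ΔCC centres that could be placed, so its limits were set by the library with the most centres. The range covers part of the cluster only. Hoxd1, outside it, had 2 peaks in GFP, 6 in WT, 5 in ΔMBD and 4 in ΔCC. The WT peak lay at -9389 bp, near Evx2, and the ΔMBD peaks at -9752 bp and 13982 bp, the latter near Hoxd11. Peak numbers followed position at every gene with at least 2 peaks in GFP, WT and ΔCC and at 909 of 910 in ΔMBD. In WT the peak at Evx2 was number 2125 and the peak at Hoxd3 number 2126, so no other WT peak was centred between them if the numbers follow position between genes too. In ΔMBD the HoxB numbers passed from 677, at Hoxb5 and Hoxb6, to 682, at Hoxb2. In WT they passed from 633, at Hoxb7 and Hoxb8, to 636, at Hoxb2. On the same condition, peaks with the numbers between were centred in these stretches, which hold Hoxb3 and Hoxb4. They were linked to no Hox gene. Widths are not given, and a broad peak is listed only at the nearest gene on each side, within 5 kb of its midpoint. A Hox gene without a listed peak was therefore not shown to lack SUZ12.

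**Figure D3:**
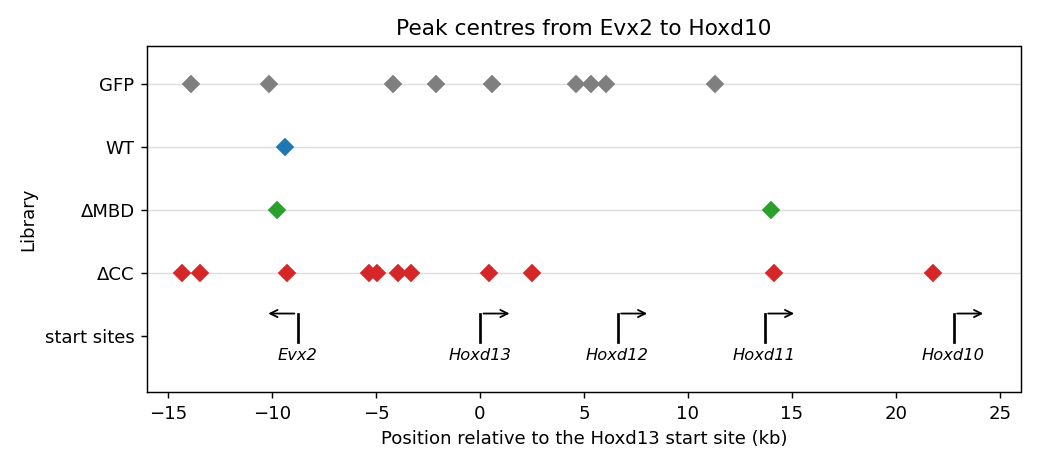
Peak centres (diamonds) of the libraries GFP, WT, ΔMBD and ΔCC (y axis) from Evx2 to Hoxd10, in kb from the Hoxd13 start site (x axis), with start sites and transcription direction as arrows. There are 9 centres in GFP, 1 in WT, 2 in ΔMBD and 11 in ΔCC, in a range that ends at the outermost placed ΔCC centres and leaves out Hoxd1. Peak widths are not given.

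The number of peaks at a gene, and their distance from the start site, also varied between the lists. A gene had 1.86 peaks on average in GFP, 1.65 in WT, 1.83 in ΔMBD and 1.91 in ΔCC. The genes with the most peaks were Hoxc8 with 8 in GFP, Hoxc4 with 9 in WT, Dmbx1 with 9 in ΔMBD and Hoxc4 with 10 in ΔCC. Next in GFP were Foxd3, Hoxb3, Hoxc12 and Hoxc4 with 7 each. Other genes with many peaks in WT were Hoxb13 with 7 and Hoxd1 and Isl1 with 6. In ΔMBD they included Hoxb13 and Vax2 with 7 and Bahd1 with 6. In ΔCC they included Hoxc8 and Wnt10a with 8 and Ebf1 and Foxd3 with 7. Of the GFP peaks listed within 5 kb of a gene, 46.2% (interval 44.0 to 48.5) were centred within 1 kb of a start site. The same share was 52.6% (50.7 to 54.5) in WT, 49.3% (47.5 to 51.1) in ΔMBD and 47.1% (45.0 to 49.2) in ΔCC. Between 66.5% and 69.3% of the peaks listed within 5 kb in each library lay at or downstream of the closest start site.

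Of the cell cycle inhibitors, Cdkn1c was listed in every library and Cdkn2a in every library but GFP, with 4 peaks in WT, 2 in ΔMBD and 1 in ΔCC. Cdkn1a and Cdkn2b were in none. In each library the intervals of the trophectoderm, endoderm, mesoderm, neuroectoderm and ligand lists overlapped those of the other libraries.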

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

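The tests of joined peaks in WT, of joined peaks with ΔCC in place of GFP, of SUZ12 absence at Hox genes and of the peaks far from their genes were chosen after the results had been seen. The tests of sensitivity, moved peak centres and joined peaks in ΔMBD with GFP were not, but the tests of moved centres by distance were added after other results were known.

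Peaks listed over 5 kb from a gene entered no comparison of lists. They numbered 10 in GFP, 3 in WT, 6 in ΔMBD and 16 in ΔCC, and were listed at Evc2, 8.93 to 8.95 Mb away, and at 6 olfactory receptor genes, about 11.3 Mb away. Of these 35 peaks, 85.7% were also listed within 5 kb of another gene, which was Shh for the Evc2 peaks and Evx2, Hoxd10, Hoxd11, Hoxd12 or Hoxd13 for the others. These values are consistent with curated regulatory domains of the association tool, in which case the peaks belong to the Shh and HoxD regions. No biological explanation was tested.

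For genes listed in WT and missing from GFP or ΔCC, a shift of peak centres past 5 kb was argued against as the main account: of WT genes with 1 peak, 45.1% (interval 41.2 to 49.0) were listed in GFP where the WT centre lay within 1 kb of the start site and 65.6% (59.6 to 71.2) where it lay farther, and in ΔCC the shares were 52.4% (48.5 to 56.4) and 70.7% (64.9 to 76.0). Of the WT-not-GFP genes, 12.7% had a neighbouring gene listed in GFP, against 18.2% of random WT genes (15.9 to 20.5), a weaker test because random genes include neighbours that share a peak. Lower sensitivity of the GFP or ΔCC library stays open: of WT genes with at least 3 peaks 71.7% were listed in GFP and 83.3% in ΔCC, against 51.2% and 57.9% of those with 1 peak. ΔMBD had a gradient in the same direction (98.3% against 84.0%), and since a gene with more peaks has more chances to be listed and peak number is not binding strength, the gradient does not single out sensitivity. Binding that differs with the form of MBD3 therefore stays open and untested, with 1 library per group and unknown depth.

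Hox genes were listed more often in GFP and ΔCC than in WT and ΔMBD. Whether a difference in sensitivity could give this was not tested. The number of listed genes in a broad region depends on how the caller split it, so sensitivity stays open here too. Joining of neighbouring peaks into fewer, wider ones across the genome was tested at the 886 genes outside the clusters that every library listed, as the share of genes with unequal numbers that had more peaks in GFP or ΔCC. Against WT the share was 53.4% for GFP (interval 49.1 to 57.6) and 60.1% for ΔCC (56.0 to 64.2), so joining in WT stays open, although WT also had fewer peaks than ΔMBD (62.6% of unequal genes had more in ΔMBD). Against ΔMBD it was 42.6% for GFP (38.5 to 46.7), below what joining in ΔMBD would give, but lower sensitivity of GFP could lower this value by itself. The 49.6% for ΔCC (45.4 to 53.9) decides nothing, so joining in ΔMBD stays open too. Joining confined to the Hox clusters was not tested, and whether SUZ12 was absent in WT from the 16 Hox genes listed in GFP and not in WT cannot be told apart from joining, because widths and signal are not given.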

How the results depend on the processing

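No paired analysis was possible because each group has 1 library. Thresholds on fold enrichment and q value, equal list lengths, a larger minimum overlap and a fixed peak width were not run, since no strength or width is given. A window of 10 kb was not run either, since deposited pairs beyond 5 kb came from 7 genes only. Joining peaks within 1 kb and the 1 kb window for the fixed lists were chosen before the data were examined, and the other alternatives after seeing the data. Of 104 recomputed values, 62 stayed within the interval of the reported share, or within 1.5 times the reported count, and 42 moved. Using all deposited pairs, leaving out Hox genes, leaving out mitochondrial, interferon zeta and Gm-numbered genes, and joining peaks moved none. Under every gene-level alternative run, WT shared more genes with ΔMBD than with ΔCC, and more with ΔCC than with GFP. The list lengths had the same order, with 1677, 1221 and 1051 genes at 5 kb and 1214, 879 and 714 at 1 kb. A shorter list can hold fewer WT genes, so this order is not separated from list length. Read from the other list at 5 kb, the shares listed in WT were 89.3% for ΔMBD, 89.8% for ΔCC and 93.1% for GFP. With a window of 1 kb, 45.3% of WT genes were listed in GFP, 77.8% in ΔMBD and 53.6% in ΔCC. The share listed in WT was 77.2% for GFP, 77.8% for ΔMBD and 74.1% for ΔCC genes. ΔMBD held 73.7% of ΔCC genes and ΔCC 53.4% of ΔMBD genes, ΔMBD held 70.9% of WT-not-GFP genes, and 401 genes were in all libraries. Listed Hox genes were then 22 in GFP, 10 in ΔMBD and 20 in ΔCC, against 15 in WT, and lineage and ligand genes 50 in GFP, 48 in WT, 50 in ΔMBD and 44 in ΔCC; fewer peaks enter at 1 kb, and WT was no longer highest. Among genes with 2 or more peaks, 68.1% of WT genes were listed in GFP, 97.2% in ΔMBD and 75.7% in ΔCC. WT held 97.1% of ΔMBD and 94.4% of ΔCC genes, ΔMBD 94.9% of ΔCC and ΔCC 74.9% of ΔMBD genes, and of the WT-not-GFP genes 92.9% were in ΔMBD and 35% in ΔCC. Counting a neighbouring gene as a match gave 63.9% of WT genes in GFP, 92.1% in ΔMBD and 70.6% in ΔCC. WT then held 95.1% of GFP, 91.9% of ΔMBD and 92.8% of ΔCC genes, ΔMBD 93.9% of ΔCC and ΔCC 71.1% of ΔMBD genes. With peak centres within 500 bp, matched WT peaks were 30.8% in GFP, 57.7% in ΔMBD and 36.8% in ΔCC. WT matched 44.8% of GFP, 52.0% of ΔMBD and 44.8% of ΔCC peaks, ΔMBD 47.6% of ΔCC and ΔCC 35.0% of ΔMBD peaks. Depth is unknown for each library and limits every statement that a gene was not listed.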

Other observations

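Genes were also counted by family. The Nkx, Pax, Lhx, Irx, Gata, Fox, Wnt, Tbx and Sox families share members with the fixed lists, so their counts partly repeat those of the lineage and ligand lists. No test between families was made. Of the tests and counts here, that by distance of the peak centre was set before its result was seen, and the others were chosen after the gene tables had been seen. For the families, 26 symbol stems were picked by hand with their counts per library in view, not drawn from every family, so the random ranges only describe these lists. Members of the Nkx, Pax, Lhx, Irx and Gata families of transcription factors that were listed at all were listed in every library, with 12, 8, 7, 6 and 5 genes. Of 22 Fox genes listed in any library, 18 were in GFP, 21 in WT, 21 in ΔMBD and 18 in ΔCC. Of 17 Wnt genes listed in any library, 14 were in GFP, 17 in WT, 17 in ΔMBD and 16 in ΔCC. Other families of transcription factors were not listed throughout. Tbx had 9 genes listed in any library, with 7 in GFP, 8 in WT, 9 in ΔMBD and 5 in ΔCC. In the same order, Sox had 8, 10, 9 and 10 of 10 such genes, and Pou 7, 8, 8 and 7 of 8. Family members listed in no library, such as Sox1, Sox2, Tbx6 and Pou5f1, are left out of these totals.

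Solute carriers (Slc), which move small molecules across membranes, were listed at 16 genes in GFP, 34 in WT, 35 in ΔMBD and 19 in ΔCC. Of the 34 WT members, 41.2% were also in GFP and 44.1% in ΔCC. Random WT genes with the same numbers of peaks gave medians of 58.8% (95% of draws between 41.2% and 73.5%) and 64.7% (50% to 79.4%). The Galnt genes, which start O-linked glycans, were listed at 1 gene in GFP, 6 in WT, 6 in ΔMBD and 1 in ΔCC. Genes of carbohydrate sulfotransferases (Chst) were 2, 7, 7 and 5 in the same order, and semaphorins (Sema) 2, 5, 7 and 2. Potassium channel genes (Kcn) were 17, 33, 29 and 20, and their 51.5% kept in GFP lay within the range of random WT genes (42.4% to 75.8%).

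WT genes with their peak close to the start site were missing from GFP and ΔCC more often. Of 639 WT genes with 1 peak, centred within 1 kb of the start site, 288 were listed in GFP, against 179 of 273 with the centre farther away. In ΔCC the numbers were 335 of 639 and 193 of 273. No explanation of this difference was tested.

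The interferon zeta cluster, whose near-identical copies make its peaks uncertain, had 6 listed genes with 21 peaks in GFP and 24 in ΔCC, and none in WT or ΔMBD. Tbr1 had 5 peaks in GFP and 2 in ΔCC, and Cbx8, a Polycomb protein gene, had 3 and 1, with none in WT or ΔMBD. A mitochondrial peak was listed at mt-Nd1 in GFP and at mt-Nd1 and mt-Nd2 in WT, and none was listed in ΔMBD or ΔCC.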
